A study of Homo sapiens with 16 samples.

How the data were processed

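The samples were cultures of HET-1A, an immortalised human esophageal squamous epithelial cell line, kept in untreated medium or exposed to 300 µM deoxycholic acid (DCA), a secondary bile acid, for 4, 8, 12 or 24 h. Each of the 8 groups had 2 arrays, 16 in all, each hybridised with biotin-labelled material from total RNA. Per the labels' protocols, cells were grown in a supplemented bronchial epithelial medium and DCA was given in medium without supplements. The labels of the controls name untreated medium and do not say whether supplements were present. The labels call the experiments duplicates without saying whether cultures were separate, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

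The deposited values are linear signal intensity for 54675 probe sets on an Affymetrix 3' expression array. Per the submitters' processing notes, GCOS and MAS5 were used; versions, background settings and detection calls are not given in the sources used here. In the deposited table, 12 arrays had a 2% trimmed mean of 100. The other 4, replicate 1 at 4 h and at 8 h in both arms, had trimmed means between 167.2 and 214.8. The design written in advance assumed that the deposited scaling was common to all arrays. Because these 4 arrays were not on it, every array was rescaled to a trimmed mean of 100, which left the other 12 essentially as deposited, and the values as deposited were kept as an alternative.

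Probe sets were named through the platform annotation table, with symbols updated through Entrez identifiers in a RefSeq gene table, which matched 41043 probe sets. One symbol was found for 41097 probe sets, several for 1801 and none for 11777; no gene was named from the last 2 kinds. No coordinates were used, because the files name no genome build. Each of 19775 genes was represented by its probe set with the highest mean log2 value, and 14631 genes remained after requiring a signal above the array's median on at least 2 of the 16 arrays. Values were analysed as log2(signal + 5.42), where the pseudocount of 5.42 was set from 21.7, the median of all scaled values, divided by 4. Fold changes are on that scale, which understates the change of dim genes.

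Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 1 coefficient per group, all 16 arrays in the fit, 8 residual degrees of freedom and a median of 16.8 after moderation. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the genes tested, and the threshold was 0.05. The contrasts were DCA against control at each time, the mean of those 4 differences, the moderated F of the change of the DCA effect over time, the difference of the effects at 24 h and 4 h, and the moderated F of the control groups over time. For genes named for the change of effect or for control time, the adjusted p-value is that of the F test over all times. The difference of 24 h and 4 h beside it gives direction and size only. Each time has its own controls, so the 4 time-matched differences share no arrays.

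The 29 gene lists were fixed before the data were examined. They were tested with camera (preset correlation 0.01) for the 4 times and the average, 145 tests adjusted together, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took the 12 highest and 12 lowest for the average with the same sign at all 4 times, the 5 highest and 5 lowest at each time, the 6 highest and 6 lowest for the change of effect, the 5 highest and 5 lowest for control time, and the 4 members of each list with the largest average change. Values of named genes at other times are given to describe their course. Of 186 named results past the threshold, 102 had further probe sets for the gene, and in 3 (FADS2, LPCAT3 and NDUFB8) another probe set passed the threshold in the opposite direction. For 11 of the 102 no other probe set passed in the same direction: GDF15 at 4, 12 and 24 h, MIR210HG at 4 h, THAP3, HK2 and PPP1R10 for the change of effect, and XBP1, FADS2, LPCAT3 and ABCC4 on average.

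Simulated data had 14631 genes with independent noise, of which 100 were changed 1.5-fold and 100 2-fold, equally at all times. Far more genes passed in the real data, so the false calls of the simulation do not measure those there. In it the 4 h comparison recovered 34% of genes changed 1.5-fold and 62% of those changed 2-fold, with 7 false calls. The 24 h comparison recovered 34% and 64% with 5 false calls. The average recovered 66% and 88% with 11 false calls. Alternatives fixed in advance were pseudocounts of 1 and of the median, quantile normalisation, centring on array medians, no filter or a stricter one (8 arrays), every probe set, no trend, a robust fit, array weights, a replicate block, leaving out each array, each time alone, an additive model and a 2-fold minimum. Those added after the data were seen were the values as deposited, scaling on the poly(A) spike-ins, leaving out the 4 rescaled arrays or the 24 h arrays, and the ACTB 3' to 5' ratio as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.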

Results

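Gene expression was measured on 16 arrays from HET-1A cells, 2 for untreated cells and 2 for cells given 300 µM DCA at each of 4, 8, 12 and 24 h. After scaling, array medians lay between 17.6 and 27.0 signal units. The 2 arrays of a group correlated at 0.974 to 0.983 across genes. Each array correlated at 0.890 to 0.962 with the closer of the arrays of the opposite arm at the same time. Principal component 1 held 51.7% of the variance. Control groups had mean scores between -40.1 and -36.1 on it at all 4 times. DCA groups had -1.45, 29.6, 54.9 and 68.0 at 4, 8, 12 and 24 h. Component 2 held 11.1% and set the 24 h arrays of both arms apart, with scores between -33.7 and -29.6. All earlier arrays scored between -2.11 and 25.2 on component 2. The ACTB 3' to 5' signal ratio, a sign of RNA integrity, was 1.17 to 1.19 in controls up to 12 h and 1.53 ± 0.06 at 24 h (SD, n = 2). With DCA it was 1.29, 1.30, 1.55 and 2.02 ± 0.40. The poly(A) spike-ins, bacterial transcripts that the standard protocol adds before labelling, stood 1.04 ± 0.14 log2 units above the control mean on the DCA arrays at 24 h. All changes below are relative to each array's trimmed mean. Scaling on the spike-ins instead moved the median of all genes from -0.26 to -1.23 at 24 h and from -0.15 to -0.61 for the average, and for lists that passed their test, medians whose sign this turned are given with both values. Folds of dim genes depend on the pseudocount of 5.42, so values that one of 1 or of 21.7 moved by over 1.5 times are given with it too.

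**Figure D1:**
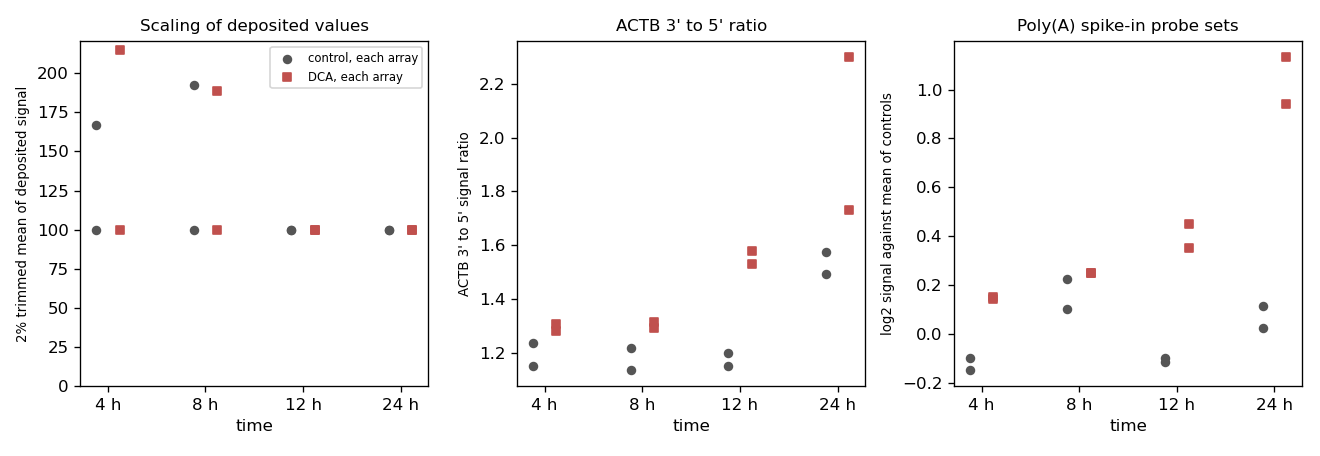
Each point is 1 array, by time and arm. The panels show the 2% trimmed mean of the deposited signal, the ACTB 3' to 5' signal ratio and the mean log2 signal of 24 poly(A) spike-in probe sets against the mean of the controls; 4 arrays have trimmed means of 167.2 to 214.8 and the other 12 lie at 100.

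The average of the 4 time-matched differences asks which genes differed between DCA and control cells over the whole course. GDF15, a stress-induced cytokine, was the most raised gene, 42.8-fold (log2 fold change 5.42 ± 0.07 SE, adjusted p = 2.69e-19). The bZIP transcription factor genes MAFF, ATF3 and DDIT3 (which encodes CHOP) were 29.4-fold, 23.4-fold and 19.1-fold higher. The cytokine genes LIF and CXCL8 (interleukin 8) were 17.3-fold and 17.1-fold higher, and that of IL6 had a log2 fold change of 3.46 ± 0.13. TRIB3, CHAC1, PPP1R15A, INHBE and GADD45A, genes known to respond to cellular stress, were 12.9-fold, 12.5-fold, 11.3-fold, 8.92-fold and 8.77-fold higher. Without the 24 h arrays CHAC1 was 22.1-fold and INHBE 14.1-fold higher, and with a pseudocount of 21.7 CXCL8 was 9.35-fold and IL6 6.82-fold higher. For each of these 12 genes, all 8 DCA arrays lay above every control array.

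The lowest average was that of COL1A1, a chain of type I collagen, 10.7-fold lower (-3.41 ± 0.07, adjusted p = 6.18e-17). The chemokine receptor gene CXCR4 was 9.45-fold lower and the chemokine gene CXCL14 had a log2 fold change of -3.17 ± 0.10. MIR210HG, the host transcript of a hypoxia-induced microRNA, was 8.75-fold lower. FAM200C, OLFM1, PPFIA4, PCTP (phosphatidylcholine transfer protein), NEURL1B, CBX7 (a Polycomb component), FAM217B and LFNG (a Notch-modifying glycosyltransferase) were 6.83-fold to 5.14-fold lower, and FAM200C 4.50-fold without the 24 h arrays. With pseudocounts of 1 and 21.7 the log2 fold changes were -4.00 and -1.97 for MIR210HG, -3.20 and -1.66 for PPFIA4, -3.07 and -1.62 for PCTP and -3.42 and -1.23 for LFNG. All 8 DCA arrays lay below every control array for each of these 12 genes. In total 9342 of 14631 genes passed the threshold, 3301 higher and 6041 lower, and 1565 of them by at least 2-fold. Centring arrays on their medians gave 4012 higher and 4795 lower, and spike-in scaling 1224 and 10683.

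At 4 h, 3281 genes differed, 1478 higher and 1803 lower. MAFF was 38.4-fold higher (5.26 ± 0.08, adjusted p = 2.13e-17), followed by CHAC1, a glutathione-degrading enzyme gene, 25.7-fold, GDF15 24.8-fold, ATF3 23.8-fold and LIF 20.5-fold. The other probe set of GDF15, a dim one, was not called at 4 h (0.96, adjusted p = 0.288). KLHL21, a cullin adaptor gene, was 10.1-fold lower, MIR210HG 8.80-fold, the chaperone gene HSPA2 7.43-fold, PCTP 7.39-fold and ZC3HAV1L 6.54-fold. PCTP was 13.2-fold lower without DCA 4 h replicate 1, 4.14-fold without replicate 2 and 14.2-fold without the 4 rescaled arrays. With pseudocounts of 1 and 21.7, KLHL21 was 21.9-fold and 3.99-fold lower, MIR210HG 18.2-fold and 3.74-fold and PCTP 12.8-fold and 3.64-fold, and CHAC1 was 16.1-fold higher with 21.7. The other probe set of MIR210HG was not called (-1.04, adjusted p = 0.0680). The change was at least 2-fold for 546 genes, 291 higher and 255 lower. Without the 4 rescaled arrays 1254 genes passed, without DCA 4 h replicate 1 there were 1990 and without replicate 2 there were 2106. Spike-in scaling gave 581 higher and 4389 lower.

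At 8 h, 5814 genes differed, 2310 higher and 3504 lower. GDF15 was 82.7-fold higher (6.37 ± 0.14, adjusted p = 2.61e-15), MAFF 34.9-fold, ATF3 33.3-fold, DDIT3 23.0-fold and CHAC1 22.8-fold. CXCR4 was 20.1-fold lower (-4.33 ± 0.11), MIR210HG 12.4-fold, COL1A1 10.3-fold, the vasodilator peptide gene ADM 7.66-fold and PFKFB4, a regulator of glycolysis, 7.53-fold. With a pseudocount of 21.7 GDF15 was 51.7-fold and CHAC1 14.4-fold higher and MIR210HG 5.48-fold lower, against 20.9-fold with 1. At least 2-fold changes were seen for 1483 genes. Without the 4 rescaled arrays 3664 genes passed, and median centring gave 2763 higher and 2177 lower.

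At 12 h, 7450 genes differed, 2838 higher and 4612 lower. GDF15 was 74.0-fold higher, CXCL8 36.8-fold (5.20 ± 0.33, adjusted p = 9.23e-10), MAFF 29.6-fold, ATF3 28.9-fold and LIF 26.8-fold. The CXCL8 probe set was dim in the 12 h controls, with signals of 10.7 and 10.6 below array medians of 21.9 and 20.1. Its fold and rank are therefore imprecise. The other probe set of GDF15 was not called (1.21, adjusted p = 0.0978). CXCL14 was 31.1-fold lower (-4.96 ± 0.19, adjusted p = 1.94e-12), COL1A1 18.1-fold, CXCR4 16.9-fold, PPFIA4 12.3-fold and MIR210HG 11.8-fold. With a pseudocount of 21.7 CXCL8 and LIF had log2 fold changes of 4.23 and 4.00; with 1 and 21.7 PPFIA4 was 19.7-fold and 5.62-fold lower and MIR210HG 19.7-fold and 5.32-fold. At least 2-fold changes were seen for 2898 genes, and spike-in scaling gave 1130 higher and 8066 lower.

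At 24 h, 8235 genes differed, 2813 higher and 5422 lower. CXCL8 was about 40.5-fold higher (5.34 ± 0.33, adjusted p = 4.91e-10), GDF15 22.2-fold, MAFF 18.8-fold, the Notch target gene HES1 15.2-fold and ATF3 13.1-fold. The CXCL8 probe set was dim in the 24 h controls, with signals of 13.4 and 17.8 below array medians of 27.0 and 26.8, and bright with DCA, 779 and 909. Its fold against such controls is imprecise and was 23.2 with a pseudocount of 21.7. The GDF15 log2 signal with DCA was 11.73 and 11.70, against 11.57 and 11.77 at 12 h. In controls it was 7.15 and 7.34, against 5.71 and 5.21 at 12 h. The smaller fold of GDF15 at 24 h thus came with higher controls. The other probe set of GDF15 was not called (1.11, adjusted p = 0.123). CXCL14 was 26.4-fold lower (-4.72 ± 0.19), FAM200C 23.9-fold, COL1A1 22.6-fold, NEURL1B 17.0-fold and CBX7 14.0-fold. With a pseudocount of 21.7 the log2 values were -3.96 for CXCL14, -3.32 for FAM200C (-5.36 with 1), -3.88 for COL1A1 and -2.89 for CBX7, and CBX7 was 23.8-fold lower with the ACTB ratio as a covariate. The change was at least 2-fold for 3648 genes, 993 higher and 2655 lower. On these arrays the 28S rRNA probe sets stood 2.26 ± 0.16 log2 units above the control mean, against 0.20 ± 0.11 in the 24 h controls. Median centring gave 3389 higher and 4158 lower, and spike-in scaling 523 and 11546.

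**Figure D2:**
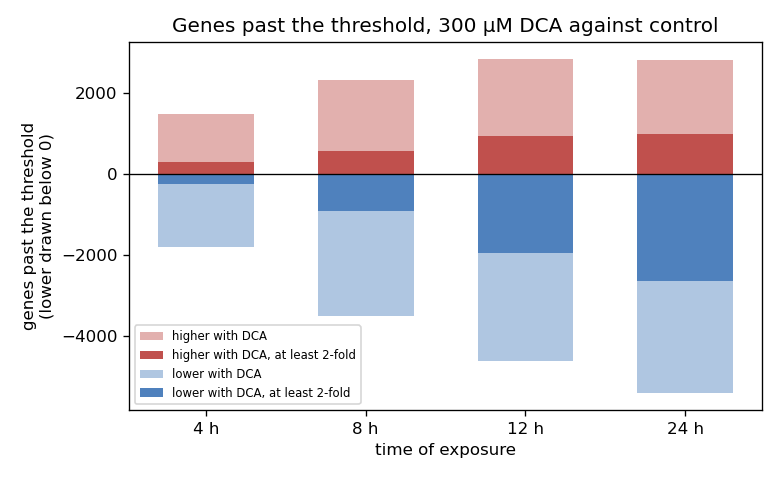
Bars give the number of genes past the threshold at each time, higher drawn above 0 and lower below it, with the dark part for changes of at least 2-fold. Totals are 3281, 5814, 7450 and 8235 at 4, 8, 12 and 24 h.

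Across the times, 862 genes were higher and 1097 lower at all 4. Of the genes higher at 4 h, 943 were also higher at 24 h, where independent lists would share 284, and of those lower at 4 h, 1302 were lower at 24 h, against 668. Another 182 genes went from higher to lower and 168 from lower to higher. Across genes, which are not independent replicates, log2 fold changes at 4 h and 24 h correlated at 0.44 and those at 12 h and 24 h at 0.79.

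List counts stand against all genes tested, of which 22.4%, 39.7%, 50.9% and 56.3% passed at 4, 8, 12 and 24 h and 63.9% for the average. Of the 35 measured ATF4 and CHOP targets, which serve amino acid supply and the integrated stress response, 30, 35, 33 and 30 were higher at 4, 8, 12 and 24 h, and 32, 35, 34 and 30 when adjusted over the list alone. None was lower before 24 h and 1 was at 24 h. Their median log2 fold changes were 0.88, 1.82, 2.08 and 1.35 (camera adjusted p from 9.60e-34 to 8.52e-18). GDF15, ATF3, DDIT3 and TRIB3 led the list. Of 23 genes of the ATF6 and XBP1 branch of the unfolded protein response, 3, 16, 16 and 15 were higher and 3, 1, 1 and 3 lower, with higher counts of 3, 17, 16 and 15 adjusted over the list alone. The transcription factor gene XBP1 was 5.49-fold higher on average, HERPUD1 4.35-fold, the endoplasmic reticulum chaperone gene HSPA5 2.31-fold and SELENOS 2.04-fold. The other, dimmer probe set of XBP1 was not called (-0.54, adjusted p = 0.0680). The list passed at 8, 12 and 24 h with either correlation, while its 4 h call (adjusted p = 0.0333) was lost with an estimated correlation (adjusted p = 0.137). Its 24 h median was 0.81, or -0.16 with spike-in scaling and 0.45 with quantile normalisation, its 4 h median 0.14, or -0.13 and 0.08, and its median for the average 0.37, or -0.08.

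Immediate early and AP-1 genes were most raised at 4 h, when 21 of 24 were higher and 1 lower, also adjusted over the list alone, with a median of 1.89. At 24 h 13 were higher and 5 lower, also adjusted over the list alone, with a median of 0.94, or -0.03 with spike-in scaling. EGR1 was 7.73-fold, FOSL1 6.89-fold and MYC 6.79-fold higher on average, and EGR1 13.1-fold without the 24 h arrays. Of 18 feedback targets of the ERK pathway, 12, 14, 15 and 14 were higher at the 4 times, and 13, 14, 15 and 15 adjusted over the list alone. At 24 h 1 was lower, also adjusted over the list alone, which called 1 at 8 h too. IER3 was 6.76-fold, ETV5 6.08-fold, PHLDA1 5.46-fold and the EGF-family ligand gene EREG 5.45-fold higher on average, EREG 9.55-fold and 2.75-fold with pseudocounts of 1 and 21.7. Both lists passed at every time with either correlation. Of 17 TGF-beta targets, 10 were higher and 1 lower at 4 h, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.08e-08, adjusted p = 0.00204 with an estimated correlation). CCN2 was 4.71-fold, BHLHE40 4.50-fold and PMEPA1 3.06-fold higher on average, while BMP4 was 4.36-fold lower, or 2.62-fold with a pseudocount of 21.7. That list did not pass at 8, 12 or 24 h, and its average call (median 0.18, or -0.28 with spike-in scaling, 0.29 with quantile normalisation and 0.30 with median centring, adjusted p = 0.0291) was lost with an estimated correlation (adjusted p = 0.0951).

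Of 22 measured NF-kB targets and inflammatory cytokines, 8, 9, 14 and 10 were higher at the 4 times and 9, 9, 15 and 9 adjusted over the list alone. The list passed at each time with either correlation, with a 24 h median of 0.62, or -0.35 with spike-in scaling. At each time 1 of its genes was lower, or 2, 1, 1 and 1 adjusted over the list alone. LIF, CXCL8, IL6 and IER3 led it. Of 25 interferon-stimulated genes, 4, 8, 16 and 17 were higher and 4, 5, 4 and 5 lower at 4, 8, 12 and 24 h. Adjusted over the list alone, 4, 9, 16 and 17 were higher and 6, 5, 4 and 5 lower. For the average 16 were higher and 6 lower, also adjusted over the list alone. IFIT2 was 5.29-fold, IFIT1 3.22-fold, IFIT3 3.01-fold and the RNA sensor gene RIGI 2.54-fold higher on average. The list did not pass at 4 h (adjusted p = 0.521) and passed at 12 and 24 h with either correlation, with medians of 0.86 and 0.84 (-0.13 at 24 h with spike-in scaling). Its 8 h call (adjusted p = 0.0107) was lost with an estimated correlation (adjusted p = 0.0760).

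Of 22 NRF2 targets, 3, 10, 15 and 13 were higher and 4, 4, 4 and 2 lower at the 4 times. Adjusted over the list alone, 4, 11, 15 and 13 were higher and 6, 5, 4 and 2 lower. At 4 h the median was -0.21 and the list did not pass (adjusted p = 0.602). The cystine transporter gene SLC7A11 (also on the ATF4 and CHOP list) was 3.59-fold, NFE2L2 3.23-fold, HMOX1 2.50-fold and TXNRD1 2.29-fold higher on average. The list passed from 8 h on with either correlation, with a 24 h median of 0.74, or -0.23 with spike-in scaling, and a median of 0.37 for the average, or -0.08. Heat shock genes passed at 24 h, when 10 of 17 were higher and 2 lower, or 11 and 2 adjusted over the list alone, with a median of 1.09, or 0.53 with quantile normalisation (adjusted p = 0.0283 with an estimated correlation). CHORDC1 was 2.19-fold, DNAJB1 1.92-fold and HSPH1 1.73-fold higher on average and DNAJB6 2.69-fold lower. Its call for the average (median 0.28, or -0.18 with spike-in scaling, adjusted p = 0.00744) was lost with an estimated correlation (adjusted p = 0.126). Of 9 metallothionein-list genes, 7 were higher and 1 lower at 12 h and at 24 h, also adjusted over the list alone, among them MT1H and MT2A, 1.48-fold and 1.47-fold on average. The zinc exporter gene SLC30A1 was 3.87-fold higher and MT3 1.51-fold lower. The list's calls from 8 h on, with a 24 h median of 0.96 (-0.0041 with spike-in scaling, 0.51 with quantile normalisation) and a median for the average of 0.45 (-0.01), were lost with an estimated correlation (adjusted p = 0.279, 0.161 and 0.0935 at 8, 12 and 24 h and 0.134 for the average), and spike-in scaling ended the calls of MT1H and MT2A.

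Ribosome biogenesis and nucleolar genes were higher from 8 h on. Of 24, 4, 14, 21 and 23 were higher and 2, 1, 1 and 1 lower at 4, 8, 12 and 24 h, or 4, 15, 21 and 23 and again 2, 1, 1 and 1 adjusted over the list alone, with medians of -0.06, 0.51, 1.02 and 1.28. NOP16 was 2.98-fold, the RNA helicase gene DDX21 2.82-fold, WDR43 2.68-fold and RRP12 2.25-fold higher on average. The list passed from 8 h on with either correlation. Cytosolic ribosomal protein genes had medians of 0.14, 0.13, 0.39 and 0.54, which spike-in scaling turned to -0.13 at 4 h, -0.12 at 12 h and -0.43 at 24 h. Quantile normalisation left little of them, with medians of 0.0099, 0.054, 0.044 and 0.096, and 3 genes higher at 12 h and 7 at 24 h. None of the 26 passed at 4 or 8 h, 24 were higher at 12 h and 26 at 24 h, with 25 and 26 adjusted over the list alone. RPL14, RPS9, RPS12 and RPL32 were 1.34-fold to 1.26-fold higher on average and had negative values with spike-in scaling. The list's calls at all times were lost with an estimated correlation (adjusted p = 0.693, 0.695, 0.458 and 0.347 at 4, 8, 12 and 24 h). For the average the median was 0.30, or -0.16 with spike-in scaling and 0.05 with quantile normalisation, and that call was lost too (adjusted p = 0.381 with an estimated correlation). Of 27 proteasome subunits, 14 were higher and 5 lower at 24 h, or 16 and 6 adjusted over the list alone. The median was 0.28, or -0.69 with spike-in scaling, 0.06 with quantile normalisation and 0.47 with median centring, and the call (adjusted p = 0.00172) was lost with an estimated correlation (adjusted p = 0.408). On average PSMD14 was 1.39-fold higher and PSMD3, PSMB2 and PSMA7 were 1.49-fold, 1.43-fold and 1.34-fold lower, with no call of PSMD14 under spike-in scaling.

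Mitotic genes were lower from 8 h on. Of 30, 15, 24 and 22 were lower and 1, 1 and 2 higher at 8, 12 and 24 h, or 15, 24 and 24 and 1, 1 and 3 adjusted over the list alone, with medians of -0.26 (-0.11 with median centring), -0.66 and -0.61. The mitotic kinase gene PLK1 was 2.79-fold lower on average, and the kinesin genes KIF20A, KIF11 and CENPE were 2.58-fold, 1.84-fold and 1.77-fold lower. The list's calls (adjusted p = 1.38e-05 at 12 h) were lost with an estimated correlation (adjusted p = 0.217, 0.0743 and 0.137 at 8, 12 and 24 h and 0.155 for the average). DNA replication genes went both ways. At 4 h 11 of 32 were lower and 2 higher, or 12 and 2 adjusted over the list alone, and at 24 h 16 were higher and 8 lower, or 16 and 10 adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.251 and 0.212), and the 24 h median of 0.23 was -0.74 with spike-in scaling, 0.07 with quantile normalisation and 0.42 with median centring. The licensing genes CDC6 and CDT1 were 2.96-fold and 1.94-fold higher on average and UHRF1 and POLE2 1.84-fold and 1.77-fold lower. In the untreated cells 23 of the 32 replication genes passed the F test over time with lower values at 24 h than at 4 h. Of the 30 mitotic genes 22 passed it with higher ones.

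Of 24 genes of hypoxia and glycolysis, 10, 18, 16 and 12 were lower and 2, 2, 3 and 8 higher at the 4 times, and 12, 18, 16 and 12 were lower and 2, 2, 3 and 8 higher adjusted over the list alone. The list passed at 4, 8 and 12 h, and with an estimated correlation at 8 h alone (adjusted p = 0.0315, against 0.112 at 4 h and 0.155 at 12 h). PFKFB4 and ADM were 4.03-fold and 3.07-fold lower on average, while VEGFA (also on the ATF4 and CHOP list) and the glucose transporter gene SLC2A3 were 5.82-fold and 3.09-fold higher. At 24 h the list's median was -0.39 (-0.20 with median centring), its mean 0.15 and the direction of its test up (adjusted p = 0.587). Of 27 respiratory chain genes, 6, 16, 20 and 13 were lower, 6, 17, 20 and 15 adjusted over the list alone, and 4 were higher at 24 h, also adjusted over the list alone. CYC1, COX6C, NDUFB8 and NDUFB3 were 1.58-fold to 1.52-fold lower on average. Other probe sets of NDUFB8 were called in both directions. That list's calls at 8 and 12 h were lost with an estimated correlation (adjusted p = 0.356 at both), as was that for the average (adjusted p = 0.509 with an estimated correlation). At 4 h, of 21 cholesterol synthesis and SREBP2 target genes, 11 were higher and 2 lower, or 11 and 3 adjusted over the list alone. The list passed then (adjusted p = 8.61e-05, and adjusted p = 0.0231 with an estimated correlation). The call at 8 h and that for the average (median 0.41, or -0.05 with spike-in scaling and 0.24 with quantile normalisation) were lost with an estimated correlation (adjusted p = 0.0968 and 0.126). SC5D was 2.57-fold higher on average, while TM7SF2, LSS and FADS2 were 3.96-fold, 3.66-fold and 2.67-fold lower. The other, dimmer probe set of FADS2 was called higher (0.80, adjusted p = 0.000528). At 12 h and 24 h, where the list did not pass, its medians were 0.26 and 0.11, or -0.24 and -0.85 with spike-in scaling, and its means -0.02 and -0.16; quantile normalisation also turned the 24 h median (-0.03).

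Of 17 glucocorticoid receptor targets, 7 were higher and 2 lower at 4 h, or 7 and 3 adjusted over the list alone (adjusted p = 0.00184, lost at adjusted p = 0.104 with an estimated correlation), with a median of 0.19, or -0.08 with spike-in scaling. The call for the average, with a median of 0.28, or -0.18, was lost too (adjusted p = 0.248). DUSP1, CEBPD, ERRFI1 and TSC22D3 were 3.40-fold, 3.07-fold, 2.52-fold and 1.91-fold higher on average. The remaining 10 lists gave no camera call at any time or for the average, and in several of them the median, the mean and the test differ in sign, as for the p53 targets on average (median -0.04, or 0.08 with median centring, and mean 0.36). Among 20 p53 targets, 9 were higher and 10 lower on average, 10 and 10 adjusted over the list alone. GADD45A, PMAIP1, SESN2 (also on the ATF4 and CHOP list) and TNFRSF10B were higher. Among 24 apoptosis regulators 6 were higher and 10 lower, also adjusted over the list alone, near the shares of all genes (3301 higher and 6041 lower of 14631). PMAIP1 and the death receptor genes TNFRSF10B and TNFRSF10A were 3.82-fold, 2.91-fold and 2.84-fold higher and FADD 2.46-fold lower. Among 26 DNA repair genes 12 were higher and 8 lower, also adjusted over the list alone. The base excision repair genes NTHL1, OGG1 and PARP1 were 2.40-fold, 1.68-fold and 1.65-fold lower and UNG 1.64-fold higher. Among 28 autophagy and lysosome genes 13 were higher and 10 lower, also adjusted over the list alone, with MAP1LC3B 2.67-fold, GABARAPL1 2.59-fold and NPC1 1.84-fold higher and ATG9A 1.96-fold lower.

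The lists of cell identity and bile acid handling gave no camera call either. Many members of the bile acid and squamous lists were not among the genes tested, so this covers only the members measured. Of 22 measured markers of columnar and Barrett's epithelium, 2 were higher and 5 lower on average, also adjusted over the list alone. KRT19, MUC1 and AGR2 were 2.83-fold, 2.23-fold and 2.19-fold lower, and FOXA2, a foregut transcription factor gene, 2.36-fold higher. Of 15 squamous markers 1 was higher and 7 lower, or 1 and 6 adjusted over the list alone, with SOX2 3.21-fold and S100A8 1.87-fold lower (2.85-fold with the ACTB ratio as a covariate) and JUP 1.63-fold higher. SPRR3 (-0.59 ± 0.25, adjusted p = 0.047) stood at the threshold, and leaving out any 1 of 12 arrays ended its call, DCA 8 h replicate 2 with the smallest value left (-0.43, adjusted p = 0.134). Of 19 junction and mesenchymal genes 6 were higher and 8 lower, also adjusted over the list alone, with SPARC 3.22-fold lower and CLDN1 and ZEB1 2.02-fold and 1.77-fold higher. Of 14 markers of other cell types, 5 were lower and none higher, also adjusted over the list alone, with COL1A1, ENO2 and THY1 10.7-fold, 2.49-fold and 2.03-fold lower; CD3E had a log2 difference of 0.47 ± 0.25 and was not called, though it was without control 8 h replicate 2 (0.64) or control 24 h replicate 1 (0.61). Of 9 bile acid receptor, transporter and FXR target genes, 3 were lower, also adjusted over the list alone, namely CYP27A1 (2.27-fold), S1PR2 (1.58-fold) and ABCC4 (1.37-fold, with neither of its other probe sets called); CYP3A4 had 0.43 ± 0.29 and was not called, though it was without control 4 h replicate 1 (0.74). Of 8 LXR targets 1 was higher and 4 lower, or 2 and 5 adjusted over the list alone. LPCAT3, NR1H3 and APOE were 1.76-fold, 1.68-fold and 1.66-fold lower and ABCA1 1.37-fold higher, the last not with spike-in scaling (-0.01). The direction of LPCAT3 is unsettled, since its other probe set, nearly as bright, was called higher (0.35, adjusted p = 0.0302).

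**Figure D3:**
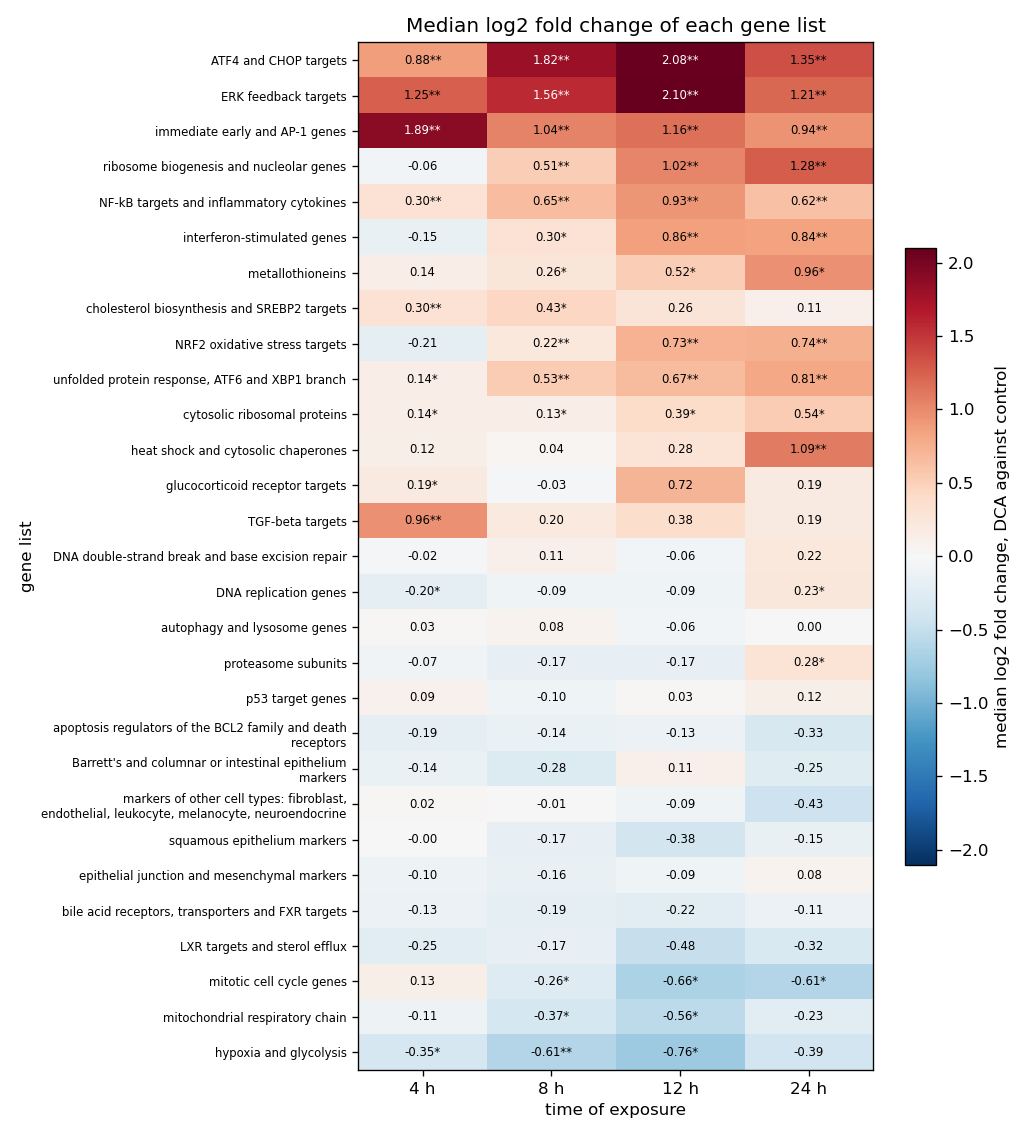
Cells give the median log2 fold change, DCA against control, of each of the 29 gene lists at each time, with colour for its size. One asterisk marks a camera call at an adjusted p under 0.05 and 2 mark a call also made with an estimated correlation; the ATF4 and CHOP targets run from 0.88 at 4 h to 2.08 at 12 h and 1.35 at 24 h.

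The change of the DCA effect over time shows which differences from control grew or shrank. A change in either arm can move it. Its F test over all times passed for 5958 genes, 2239 with a larger (more positive) effect at 24 h than at 4 h and 3719 with a smaller one. The effect on CXCL8 had a log2 fold change of 1.83 at 4 h and 5.34 at 24 h, a difference of 3.51 ± 0.47 (F test adjusted p = 3.93e-05). The 4 h value rests on controls that differ: without control 4 h replicate 1 it was 1.05 and the difference 4.29, without replicate 2 they were 2.61 and 2.74, and without the 4 rescaled arrays the difference was 4.13. The effect on IFIT3, an interferon-induced gene, went from -0.52 to 2.77, that on IGFBP3, which binds insulin-like growth factors, from -0.26 to 2.96, that on the hexokinase gene HK2 from -0.19 to 3.02, and that on the calcium-binding protein gene S100P from 0.23 to 3.35. The S100P difference of 3.13 was 3.75, and the 24 h value 3.98, without control 24 h replicate 1, and they were 2.50 and 2.73 without replicate 2. THAP3 went from -1.37, not called, to 2.13; its 4 h value was called without control 4 h replicate 2 (-1.90), and without either control 12 h array at the same value. Other, dim probe sets of HK2 and THAP3 were not called (HK2 -0.89 and -0.22, THAP3 0.87), nor was that of PPP1R10 (-1.19). In the other direction CXCL14 went from -0.41, not called, to -4.72, APLP1 from 0.19 to -3.38, the phosphatase subunit gene PPP1R10 from 1.89 to -1.53 and FAM200C from -1.18 to -4.58. IL21R went from 2.16 to -1.98, with 1.41 at 4 h and a difference of -3.39 without control 4 h replicate 1 and 2.90 and -4.88 without replicate 2, against a difference of -4.13 with all arrays and -3.30 without the 4 rescaled ones. CHAC1 went from 4.68 to 1.20, while in untreated cells IL21R and CHAC1 were 2.26 and 2.72 higher at 24 h than at 4 h. With DCA the CHAC1 log2 signal was 9.33 and 9.41 at 4 h and 8.58 and 8.64 at 24 h. With pseudocounts of 1 and 21.7 the difference for THAP3 was 4.67 and 2.04, for IL21R -4.78 and -2.89 and for FAM200C -4.13 and -2.28. With 21.7 it was 2.36 for S100P, -3.58 for CXCL14, -2.61 for APLP1 and -2.89 for CHAC1. In untreated cells HK2, S100P and IGFBP3 had log2 differences of -1.50, -1.22 and -1.16 between 24 h and 4 h. The single contrast of 24 h with 4 h called 5654 genes, 2026 higher and 3628 lower. Median centring gave 2266 and 2477 and spike-in scaling 402 and 8272, and for the F test spike-in scaling gave 749 and 8895.

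**Figure D4:**
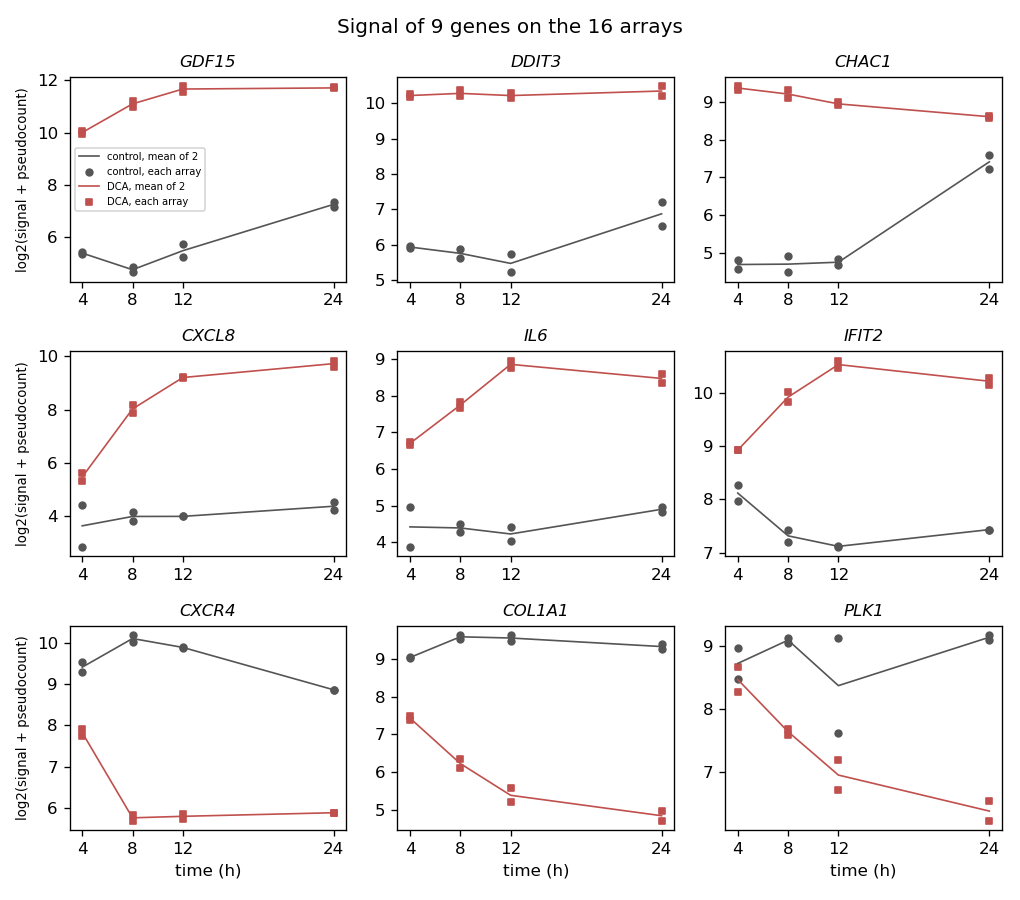
Points are the log2(signal + pseudocount) of 9 genes on each of the 16 arrays, by time in hours, and lines join the means of the 2 arrays of each arm. CHAC1 rises by 2.72 in the controls between 4 h and 24 h, and COL1A1 has a log2 fold change of -4.50 with DCA at 24 h.

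Untreated cells were also compared over time. The 24 h and 4 h control arrays differed in the ACTB ratio, 1.53 ± 0.06 against 1.19 ± 0.06 (SD, n = 2). Their hybridization controls stood at 0.78 ± 0.44 and -0.40 ± 0.06 log2 units against the control mean. Time in culture cannot be told apart from such differences between arrays. Between 4 h and 24 h, RASEF, a Rab family gene, rose 25.3-fold (4.66 ± 0.19, adjusted p = 2.68e-11 for the F test over all times), the zinc finger gene ZNF595 10.2-fold, CHAC1 6.61-fold and the non-coding transcripts LOC101927166 and HCG27 6.41-fold and 6.13-fold. The acute phase gene SERPINA3 fell most, 9.22-fold (-3.20 ± 0.10, F test adjusted p = 7.74e-12), followed by GGT5 7.27-fold, KLHL21 6.10-fold, the BCL2-family gene BIK 4.88-fold and SNORA21 4.59-fold. With pseudocounts of 1 and 21.7 ZNF595 was 17.6-fold and 4.65-fold higher, HCG27 10.7-fold and 2.89-fold, GGT5 13.7-fold and 3.21-fold lower and SNORA21 9.72-fold and 2.14-fold, and with 21.7 KLHL21 was 3.28-fold and BIK 2.86-fold lower. By the F test control groups differed over time for 3587 genes, 1815 with higher and 1772 with lower values at 24 h than at 4 h, 272 of them by at least 2-fold. A gene may pass that test through 8 h or 12 h alone. Of the lists, 20 of 26 ribosomal protein genes and 16 of 21 cholesterol synthesis and SREBP2 target genes passed it with higher values at 24 h than at 4 h. Lower values went with 15 of 24 ribosome biogenesis genes that passed. Without control 24 h replicate 2 the count was 2264, without the 4 rescaled arrays 1703, and with the ACTB ratio as a covariate 2014. Median centring gave 642 higher and 3530 lower, and spike-in scaling 1557 and 3719.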

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

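The tests of the spike-in pattern were chosen only after the result was seen; the tests of the change over time and the splits were planned. The test of the change of the DCA effect over time passed for 5958 genes. The largest differences of the effect, 24 h minus 4 h on the log2 scale, were 3.51 for CXCL8, 3.50 for THAP3, 3.29 for IFIT3, 3.22 for IGFBP3, 3.21 for HK2 and 3.13 for S100P. The lowest were -4.32 for CXCL14, -4.13 for IL21R, -3.57 for APLP1, -3.48 for CHAC1, -3.42 for PPP1R10 and -3.39 for FAM200C. Without control 4 h replicate 1 the values were 4.29 for CXCL8 and -3.39 for IL21R and without replicate 2 they were 2.74 and -4.88, while that for S100P was 3.75 without control 24 h replicate 1 and 2.50 without replicate 2. Among probe sets without a gene symbol, which the comparisons leave out, 1962 of 5170 tested passed for the average, 641 higher and 1321 lower. For the average effect, 1 of 100 splits of the arrays within times (drawn from 648) gave as many genes, the real one with 9342; the highest other split gave 8303. The median of the other splits was 0 genes. Most splits mix the arms within a group, which raises the spread within groups, so few genes can pass. Splits that swap the arms at a whole time were not left out. The result shows that the arrays separate by arm, and says nothing about chance differences between cultures if the duplicates are technical.

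The poly(A) spike-ins stood at 0.15, 0.25, 0.40 and 1.04 ± 0.14 log2 units above the control mean on the DCA arrays at 4, 8, 12 and 24 h (controls -0.12, 0.16, -0.11 and 0.07), and the 28S rRNA probe sets at -0.06, -0.06, -0.03 and 2.26 ± 0.16 (controls 0.03, 0.20, -0.42 and 0.20; SD, n = 2). Brighter hybridization is argued against, since the hybridization controls differed by -0.13 ± 0.32 between DCA and control at 24 h and the spike-ins by 0.97 ± 0.11 (SE). RNA degradation stays open: DCA arrays at 12 h and controls at 24 h had close ACTB ratios (difference 0.02 ± 0.05) while the spike-ins differed by 0.33 ± 0.07, but the GAPDH ratio differed too (0.12 ± 0.04); from 12 h to 24 h with DCA the spike-ins rose by 0.64 ± 0.11 while the GAPDH ratio, 1.27 and 1.22, differed by -0.05 ± 0.03, which goes against degradation for that step, and the ACTB ratio by 0.46 ± 0.29, which leaves it open. A lower share of mRNA in the total RNA of DCA cells may also account for the brighter spike-ins, since the 28S probe sets were 2.06 ± 0.14 higher than in 24 h controls. Up to 12 h they were near the mean of all controls with DCA, when the spike-ins already stood above it. This timing depends on the baseline. Against controls of the same time, the 28S probe sets were lower with DCA at 4 and 8 h. At 12 h they were higher, -0.03 against -0.42 ± 0.33. The spike-ins were higher at 4, 8 and 12 h, at 8 h by little (0.25 against 0.16 ± 0.09). The RNA input per array is not given in the sources used here. These 2 explanations cannot be told apart, because both predict brighter spike-ins and no value here measures mRNA per cell.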

How the results depend on the processing

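The alternatives chosen only after the result was seen were the values as deposited, spike-in scaling, leaving out the 4 rescaled or the 24 h arrays, and the ACTB covariate. Where counts moved by over 1.5 times, the cause was not tested, except that a 2-fold minimum, more probe sets and fewer arrays change counts by construction. The values as deposited do so too, since 4 arrays off the common scale add to the spread between duplicates. Counts are given for 4, 8, 12 and 24 h, the average, 24 h minus 4 h, the change over time and control time, in that order. A 2-fold minimum left 546, 1483, 2898, 3648, 1565, 2498, 2315 and 272, and testing every probe set gave 6160, 10881, 15008, 16587, 19754, 10201, 10694 and 6571. The values as deposited gave 79 (70 higher, 9 lower), 230 (130 and 100), 948, 1624, 3789, 82 (11 and 71), 31 (6 and 25) and 20 (7 and 13). Spike-in scaling gave 4970 at 4 h, 8674 for 24 h minus 4 h and 9644 for the change over time. Without the 4 rescaled arrays the counts were 1254 at 4 h, 3664 at 8 h and 1703 for control time, and with the ACTB covariate control time gave 2014. Leaving out 1 array at a time, where a lone array is assumed to vary like the others, gave 1990 to 3404, 4485 to 5981, 6393 to 7581, 7272 to 8348, 9010 to 9295, 4836 to 5671, 5111 to 5922 and 2264 to 3955. The lowest at 4 h was without DCA 4 h replicate 1, with 2106 without its duplicate, and for control time without control 24 h replicate 2. Without the 24 h arrays the average gave 8370. Of 68 list calls, 39 passed with an estimated correlation, fry made 121, and camera on quantile-normalised values 60. After rescaling, replicate differences of the arms correlated weakly, at 0.10, 0.08, 0.06 and -0.03 across genes at the 4 times. All 28 pairs of groups lay within -0.11 to 0.10, the highest being the 2 arms at 4 h. The deposited scaling did go with replicate number at 4 h and 8 h, where replicate 1 of both arms was off target. Pairing by replicate number is thus neither shown nor excluded. With the replicate number as a block the counts were 3210, 5767, 7424, 8192, 9305, 5624, 5843 and 3433. Of 6110 alternative values of 188 gene results, 6046 kept direction and side of the threshold, 55 lost the call, 23 of them with the values as deposited, and 4 gained one; the stricter filter gave values for 178. Spike-in scaling reversed 5 averages, ABCA1 to -0.0087, RPL14 to -0.0396, RPL32 to -0.12, RPS12 to -0.10 and RPS9 to -0.0743. The number of arrays limits the precision.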

Other observations

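The tests of the gene families, the rescaling and the IRE1 list were chosen only after the result was seen; the ERK feedback list was fixed and tested as planned. Among 90 gene families and 5 comparisons (450 tests with camera), cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs and of which several are on the ATF4 and CHOP list, were higher in 14 of 17 on average, with a median of 0.96 (adjusted p = 1.12e-07, adjusted p = 0.194 with an estimated correlation). Translation initiation factor genes (EIF) were higher in 30 of 52 at 24 h, with a median of 0.53, or -0.44 with spike-in scaling and 0.25 with quantile normalisation (adjusted p = 3.53e-06, adjusted p = 0.194 with an estimated correlation). Collagen genes (COL) were lower in 16 of 31 at 24 h and higher in none, with a median of -0.90 (adjusted p = 0.0112, adjusted p = 0.371 with an estimated correlation). At that time 2813 of all 14631 genes were higher and 5422 lower. Tetraspanin genes (TSPAN) were lower in 13 of 18 at 24 h, with a median of -0.92 (adjusted p = 0.0206, adjusted p = 0.371 with an estimated correlation). The directions of the synthetase, collagen and tetraspanin medians were the same under every scaling tried.

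ERK feedback genes were higher on the DCA arrays, although the labels say that DCA was given in medium without supplements. Their median at 4 h was 1.25. Rescaling of the 4 arrays is argued against, since the replicate 2 arrays at 4 h, which needed none, differed by a median of 1.25. A response to DCA is a candidate explanation, but it cannot be told apart from an effect of the medium, because the labels do not say whether control medium had supplements.

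Transcripts reported as substrates of the endonuclease IRE1, a sensor of endoplasmic reticulum stress, were lower at 24 h in 6 of 6 measured: BLOC1S1 -1.68, SPARC -2.51, COL6A1 -1.64, PDGFRB -1.27, SCARA3 -1.43 and HGSNAT -2.19; the IRE1 gene ERN1 was 2.59 higher on the log2 scale. Without BLOC1S1 the median of -1.64 lay at percentile 0.27 of 10000 random lists matched on mean expression, whose median was -0.33, and at percentiles 6.42, 0.70 and 8.35 at 4, 8 and 12 h. With the ACTB ratio as a covariate the percentile of all 6 genes went from 0.07 to 0.35 at 24 h, 0.91 to 2.11 at 8 h and 0.77 to 4.05 for the average. In that fit the slope on the ratio comes only from differences between duplicates. The largest is that of the DCA 24 h arrays (2.30 and 1.73), so the fit does not decide on RNA degradation. At 4 h the percentile went from 3.75 to 9.10 and at 12 h from 4.40 to 15.19. The medians were -0.37 and -0.30 at 4 h and -0.80 and -0.56 at 12 h, against an SD of random lists of 0.18 and 0.18, and 0.35 and 0.39. They shrank by less than that SD, so this neither supports nor excludes degradation there. The 24 h pattern may reflect decay by IRE1, as a hypothesis found and tested on the same data. RNA degradation stays open, as does a general fall of transcripts for secreted and membrane proteins. The collagen median at 24 h was -0.90, and 5 genes are few.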
